A study of Saccharomyces cerevisiae with 11 samples.

How the data were processed

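The series holds 11 samples of a rim15 deletion strain of Saccharomyces cerevisiae, each measured on its own 1-colour Affymetrix yeast array. Per the labels, total RNA was extracted with hot phenol, mRNA was isolated and the labelled sample carried biotin. The deposited intensity values are linear probe-set signals that the authors made with GCOS 1.2, according to their processing notes; the background, summary and scaling settings are not given in the sources used here. The mean signal of each array without its lowest and highest 2% of probe sets was the same within 0.0311%, so the arrays had been scaled to 1 trimmed mean. The values were not log-transformed and had no lower limit.

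Samples were grouped as the labels give them into the chemostat (3 cultures) and the retentostat on days 2, 9, 16 and 20 (2 cultures each day). The retentostat arrays with the same replicate number were taken as the same culture sampled repeatedly. To check this, the deviation of each retentostat array from its day's mean was correlated across genes between days, and it gave 0.227 to 0.690 for the same number; the same numbers between the chemostat and the retentostat gave -0.209 to 0.288. Pairs of days 9, 16 and 20 gave 0.498 to 0.690, and pairs with day 2 gave 0.227 to 0.444. On days 9, 16 and 20 the culture 2 arrays share a high 3'/5' signal ratio, described in the results, which could also produce such correlations. The ranges overlap as well, so the check alone does not settle the pairing. The culture code given for each sample was the same on all retentostat arrays of a replicate number. Each chemostat array had a code of its own, and the chemostat cultures were treated as cultures of their own. Genes are not independent replicates in such a correlation. A wild-type strain belongs to the design of the study and was not analysed here.

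Of 9335 probe sets, 6504 were annotated to 1 gene, 328 to several genes, 2443 to none and 60 were controls. For each of 5656 genes the probe set with the highest mean log2 signal was used, and 79 genes at or under the floor on all arrays were left out, which gave 5577 genes. Signals under 12 were set to 12 and the values were taken to log2. Gene names come from the platform annotation, with symbols updated from a gene table. No genome build is stated, so no coordinates are given. Probe sets shared within a gene family cannot tell its members apart, and no gene was named from a probe set annotated to several genes. Folds against a group under the floor were computed against the floor and are lower bounds.

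Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes over all 11 arrays, 1 mean per group), with Benjamini-Hochberg adjustment over the genes of each comparison and a threshold of 0.05 on the adjusted p. The comparisons were each retentostat day with the chemostat, day 20 with day 2, day 9 with day 2, day 20 with day 9 and an F test over the 5 sampling points. All adjusted p-values of single genes are from limma, two-sided, with 6 residual degrees of freedom and 3.52 from the prior. This fit treats all 11 arrays as independent, although the retentostat arrays were taken as 2 cultures sampled repeatedly. The deviations of a culture from the day means, which enter the residual spread, correlated between days at 0.227 to 0.690. The 6 degrees of freedom may therefore overstate the independent information, in the F test and the tests against the chemostat too. Errors of log2 differences are moderated standard errors. With 2 or 3 arrays per group, no exact test on a single gene could reach the threshold after adjustment.

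Before the data were examined, 31 gene lists were fixed, from textbook knowledge of yeast: ribosomal proteins, ribosome biogenesis, RNA polymerases I and III, translation factors, glycogen, trehalose, Msn2/4-type stress, stationary-phase, heat-shock, oxidative-stress, G1/S, histone, G2/M, M/G1, meiosis, glycolysis, hexose transporter, gluconeogenesis, TCA cycle, respiratory chain, beta-oxidation, autophagy, proteasome, seripauperin, ergosterol, amino acid, nitrogen-catabolite-repressed, vacuolar, a-specific, alpha-specific and Rim15 signalling genes. Each was tested against all other genes with limma's camera at a preset correlation of 0.01, with adjustment over the 31 lists of a comparison. The test was repeated with an estimated correlation and with limma's fry, which asks whether a list's genes move in 1 direction on balance without comparing them with other genes. Counts adjusted over the list alone use the same p-values with adjustment within the list. The comparisons, the alternatives and the rule for named genes were also chosen before the data were examined.

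Genes were named by a fixed rule. On day 2 and day 20 against the chemostat and on day 20 against day 2, it takes the 8 largest rises and the 8 largest falls among genes past the threshold with a mean signal of at least 50 in the higher group and no overlap between the arrays of the groups. It adds up to 3 members with the smallest p from each list past its test there. In the other comparisons it takes the 3 largest in each direction. RIM15 and members of the Rim15 signalling, glycogen, trehalose, histone and mating lists may always be named. Where a comparison had under 5 calls, the 5 genes with the smallest p were named with their values.

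The alternatives were quantile scaling and scaling to the same median, log2 of the signal plus 1 or plus 32 in place of the floor, leaving out genes with a mean signal under 50, testing all probe sets except controls, an intensity trend with robust estimation, culture as a random block (correlation 0.247), the replicate number as a fixed term, culture as a fixed term within the 8 retentostat arrays, leaving out each array or each retentostat culture, only the arrays of the groups compared, and a 2-fold minimum. After the data were seen, fits without the 3 arrays whose ACT1 3'/5' ratio exceeded 10, a fit with the log2 ratio as a covariate, and the overlap of days 9, 16 and 20 alone were added.

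The procedure was tested on simulated data for day 20 against the chemostat, with 5577 genes and 50 changed genes per fold. It recovered 26% of genes changed 2-fold, 90% at 4-fold, 92% at 8-fold and 100% at 16-fold, with 6 false calls. The simulated noise was independent and of equal spread in all groups, without shared cultures, loss of 5' signal or a shift in scaling. Changes were placed only in genes with a mean log2 signal at or above the log2 of 50. These rates therefore check the procedure and do not give the error rate of the calls in the real data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.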

Results

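Transcript levels were measured with 11 one-colour Affymetrix yeast arrays in a strain of Saccharomyces cerevisiae that lacks RIM15 (YFL033C), made in the laboratory background CEN.PK113-7D. RIM15 encodes a protein kinase that acts below nutrient signalling when yeast stops dividing and enters the resting state. The cells were grown without oxygen and with glucose as the limiting nutrient. A chemostat loses cells with its outflow, so its cells divide at the dilution rate, here 0.025 per h. A retentostat filters the outflow and keeps the cells in the vessel, so that the glucose available to each cell falls and division slows. The series asks how deletion of RIM15 affects yeast under severe calorie restriction. The chemostat, taken as the start of the time course, was represented by 3 independent cultures. The retentostat was represented by 2 cultures, called culture 1 and culture 2, each sampled on days 2, 9, 16 and 20. The wild-type strain was not analysed here, so every comparison describes the mutant over time. The RIM15 probe set (YFL033C) gave signals from 0.4 to 13.9, with a mean of 4.95, and lay at or under the signal floor of 12 on 10 of the 11 arrays. Where this probe set lies within the gene is not given in the sources used here, so it checks the labels only if it lies in the deleted part.

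The deposited signals had the same trimmed mean on each array, within 0.0311%, and the median signal ran from 85.3 on chemostat array 1 to 122 on the day 20 array of culture 2. Between 15.8% and 22.9% of the probe sets on an array lay at or under the floor. Log2 signals of replicate arrays correlated across genes at 0.974 to 0.983 in the chemostat, 0.959 on day 2, 0.886 on day 9, 0.853 on day 16 and 0.965 on day 20. On 3 arrays, all of culture 2, the control probe sets for actin (ACT1) gave far more signal at the 3' end of the transcript than at the 5' end. Their 3'/5' ratio was 27.0 on day 9, 217 on day 16 and 31.8 on day 20, against 0.966 to 2.03 on the other 8 arrays. Every comparison that involves days 9, 16 or 20 therefore rests on 1 array with a high ratio and 1 without. The count of changed genes without the 3 arrays is given with each comparison. In that fit these days have 1 array each, assumed to vary like the chemostat and day 2 arrays. Its counts therefore cannot be set directly against those with all arrays. The number of arrays limits the precision throughout.

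**Figure D1:**
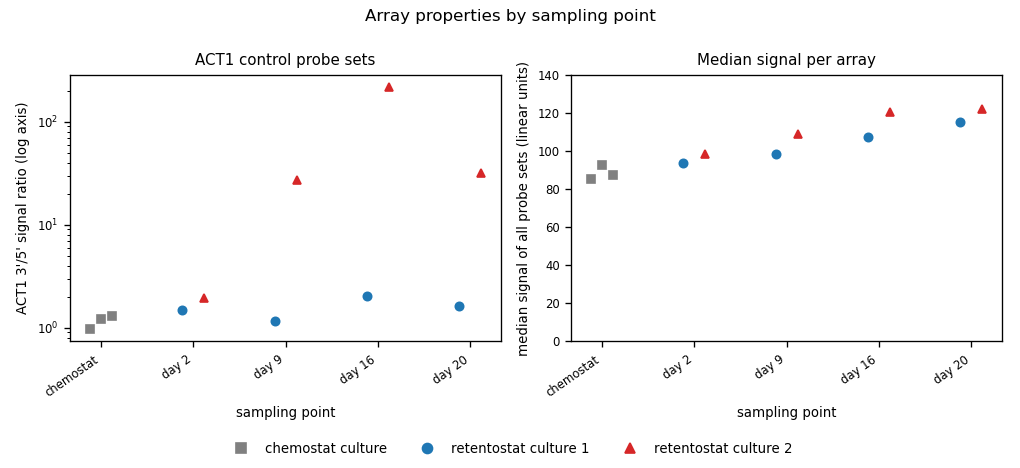
The left panel plots the 3'/5' signal ratio of the ACT1 control probe sets on a log axis and the right panel the median signal of all probe sets, for each array, by sampling point. Squares are chemostat cultures, circles retentostat culture 1 and triangles retentostat culture 2. The ratio was 27.0, 217 and 31.8 on the culture 2 arrays of days 9, 16 and 20.

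Of 5577 genes tested, 636 changed over the 5 sampling points by the moderated F test (adjusted p under 0.05), and 175 did so without the 3 arrays of high ACT1 ratio. The count was 156, 192 and 170 without chemostat array 1, 2 or 3, and 399, 1060 and 332 without the culture 1 array of day 2, 16 or 20, and 293 without the culture 2 array of day 20. The count of genes that differed from the chemostat was 1 on day 2, 842 on day 9, 1167 on day 16 and 753 on day 20. The fit shares 1 spread over all groups, but the median gene SD on the log2 scale was 0.205 in the chemostat and 0.235 on day 2. It was 0.393 on day 9, 0.422 on day 16 and 0.175 on day 20. With only the arrays of the groups compared, the counts were 618, 758 and 1942 on days 9, 16 and 20. The order of the days therefore depends on how the spread is estimated. The fit also treats the retentostat arrays as independent, although they come from 2 cultures. With culture as a random block the counts against the chemostat were 897, 1235 and 831 on days 9, 16 and 20. With the replicate number as a fixed term they were 627, 1009 and 601. Under the deposited scaling the median log2 difference of all genes from the chemostat was 0.11 on day 2, 0.25 on day 9, 0.35 on day 16 and 0.36 on day 20, whereas median scaling put it at 0.03 on day 9 and -0.04 on day 20. Gene lists were therefore tested against all other genes. The split into higher and lower calls depends on the scaling and is given with each comparison.

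**Figure D2:**
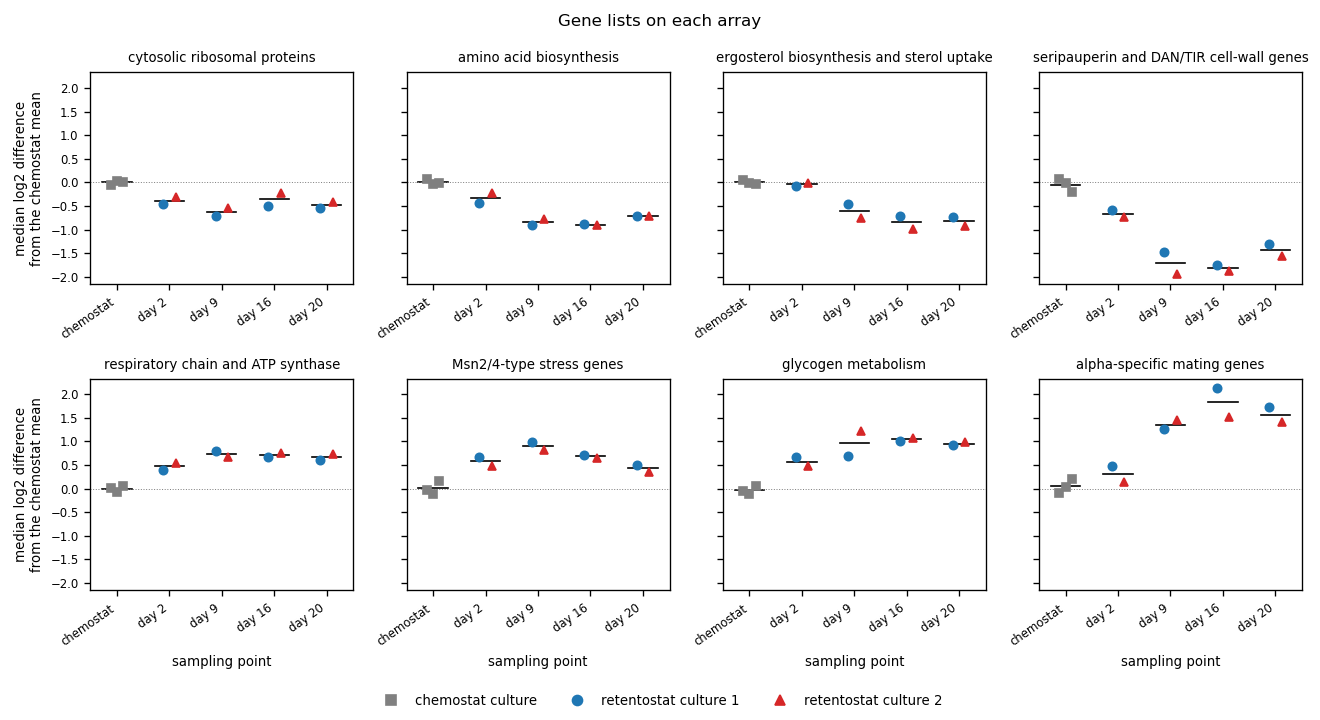
Each panel shows a gene list fixed beforehand. Points are the median log2 difference of the list's genes on an array from the chemostat mean of each gene, with chemostat cultures as squares, culture 1 as circles and culture 2 as triangles, and bars are the means of the arrays at a sampling point. Ribosomal protein, amino acid biosynthesis and seripauperin lists lay below 0 on all 8 retentostat arrays and the respiratory chain list above 0. The medians of these 8 lists against the chemostat kept their sign under quantile and median scaling.

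After 2 days of retentostat culture, 1 gene passed the threshold on its own. FMP16 (YDR070C), which encodes a mitochondrial protein, rose from a signal of 45.9 ± 7.52 (SD, n = 3) to 178 ± 7.28 (SD, n = 2), a log2 difference of 1.97 ± 0.23 (SE, limma adjusted p = 0.0490). The next smallest p-values belonged to CYC7 (YEL039C, cytochrome c isoform 2), HSP42 (YDR171W, a small heat-shock protein), GIT1 (YCR098C, a transporter of glycerophosphoinositol) and HSP30 (YCR021C, a stress protein of the plasma membrane). Their log2 differences were 1.79, 1.56, 1.69 and 1.79, and none of them passed the threshold.

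Gene lists moved on day 2 although their members did not pass singly. Among growth-related lists, the cytosolic ribosomal proteins, of which 80 of 137 could be measured, lay lower with a median log2 difference of -0.44, and 8 of the 80 lay above 0 (camera adjusted p = 4.60e-19). Amino acid biosynthesis (65 genes) had a median of -0.31 (adjusted p = 1.31e-12) and the seripauperin and DAN/TIR cell-wall genes (16 genes), typical of anaerobic yeast, a median of -0.68 (adjusted p = 2.12e-13). These 3 lists kept their calls with an estimated correlation, as did the respiratory chain and ATP synthase list, which was higher with a median of 0.42 (adjusted p = 6.50e-06). Adjusted over the list alone, 7 seripauperin genes and 1 amino acid gene passed as lower, and no ribosomal or respiratory gene passed.

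Stress and reserve lists were higher on day 2 by camera's preset correlation. The Msn2/4-type stress genes had a median of 0.54 (adjusted p = 1.09e-08, and adjusted p = 0.0675 with an estimated correlation). Heat-shock chaperones had 0.44 (adjusted p = 0.000273, and adjusted p = 0.113 with an estimated correlation). Glycogen metabolism had 0.44 (adjusted p = 0.000822, and adjusted p = 0.122 with an estimated correlation), and stationary-phase genes 0.51 (adjusted p = 0.00500, and adjusted p = 0.0719 with an estimated correlation). Trehalose metabolism had 0.56 (adjusted p = 0.0387, and adjusted p = 0.239 with an estimated correlation), nitrogen-catabolite-repressed genes 0.41 (adjusted p = 0.0426, and adjusted p = 0.173 with an estimated correlation) and a-specific mating genes 0.33 (adjusted p = 0.0454, and adjusted p = 0.272 with an estimated correlation). Adjusted over the list alone, 7 stress genes, 5 chaperones, 5 glycogen genes, 1 stationary-phase gene and 1 nitrogen gene passed as higher and 1 glycogen gene as lower. Ribosome biogenesis factors were lower with -0.15 (adjusted p = 2.73e-07, and adjusted p = 0.338 with an estimated correlation). Translation factors had -0.12 (adjusted p = 0.00500, and adjusted p = 0.0723 with an estimated correlation), RNA polymerase I and III subunits -0.20 (adjusted p = 0.0449, and adjusted p = 0.387 with an estimated correlation) and G1/S cell-cycle genes -0.11 (adjusted p = 0.0454, and adjusted p = 0.555 with an estimated correlation).

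The day 2 calls were close to the limit of the data. FMP16 lost its call when any 1 of the 11 arrays was left out and under quantile or median scaling, so that the count was then 0, and 478 genes had an unadjusted p under 0.05. Of the lists, those for RNA polymerase, trehalose, nitrogen-catabolite-repressed, G1/S, a-specific and stationary-phase genes lost their calls when 1 array was left out, all 6 without the day 2 array of culture 1 (adjusted p = 0.0504, 0.0865, 0.124, 0.432, 0.256 and 0.0865), and some also without chemostat array 2 or 3, the day 2 array of culture 2 or a day 9 array. The same 6 lists, in that order, lost their calls with genes of a mean signal under 50 left out (adjusted p = 0.0615, 0.0525, 0.0615, 0.0664, 0.0615 and 0.0586). Trehalose and nitrogen genes lost their calls without the 3 arrays of high ACT1 ratio too, which enter this comparison through the shared spread (adjusted p = 0.0770 and 0.0921).

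By day 9, 842 genes differed from the chemostat, 637 higher and 205 lower. The largest rises were in HSP30, with a log2 difference of 3.91 ± 0.27 (SE, adjusted p = 0.000384), in the uncharacterised YJR115W, with 3.25 ± 0.30, and in SNR14 (YNCE0011C), the U4 spliceosomal RNA, with 3.17 ± 0.34. The largest falls were in FIT2 (YOR382W), a cell-wall mannoprotein that helps retain iron carriers, with -3.75 ± 0.32, in SFG1 (YOR315W), a regulator of filamentous growth, with -3.60 ± 0.52, and in FIT3 (YOR383C), a relative of FIT2, with -3.31 ± 0.88 (adjusted p = 0.0345). The FIT3 call ended under quantile scaling. In the list of Rim15 signalling genes, which as a group did not pass (median 0.18, and -0.04 under quantile scaling, adjusted p = 0.868), SCH9 (YHR205W), KOG1 (YHR186C) and GIS1 (YDR096W) were higher, with 1.69 ± 0.41, 1.07 ± 0.23 and 1.10 ± 0.27, and RAS1 (YOR101W) lower, with -1.29 ± 0.29 (3 and 1 adjusted over the list alone). GIS1 and SCH9 lost their calls under quantile (adjusted p = 0.0592 and 0.0781) and median scaling (adjusted p = 0.0634 and 0.0681), and GIS1 and KOG1 without the 3 arrays of high ACT1 ratio (adjusted p = 0.0749 and 0.0688).

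Several biosynthetic lists were lower on day 9, with 20 of 65 amino acid biosynthesis genes lower and 1 higher past the threshold (32 and 2 adjusted over the list alone, median -0.91, adjusted p = 1.55e-20). In the seripauperin and DAN/TIR list 12 of 16 genes fell (13 adjusted over the list alone, median -1.73, adjusted p = 2.93e-17). Of 80 ribosomal protein genes 11 fell (9 adjusted over the list alone, median -0.57, adjusted p = 7.81e-16), and in ergosterol biosynthesis and sterol uptake 8 of 28 fell and 1 rose (9 and 2 adjusted over the list alone, median -0.50, adjusted p = 4.60e-06). Translation factors had a median of -0.44 with 1 gene lower (1 adjusted over the list alone, adjusted p = 0.000247). These 5 calls held with an estimated correlation. On the higher side, 11 of 34 respiratory chain and ATP synthase genes rose (17 adjusted over the list alone, median 0.72, adjusted p = 0.000488, and adjusted p = 0.0550 with an estimated correlation). Of 39 Msn2/4-type stress genes 14 rose (18 adjusted over the list alone, median 0.88, adjusted p = 0.000101, and adjusted p = 0.143 with an estimated correlation).

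Glycogen metabolism was higher on day 9, with 6 of 15 genes up and 1 down (7 and 1 adjusted over the list alone, median 1.02, adjusted p = 0.00826, and adjusted p = 0.199 with an estimated correlation). PIG2 (YIL045W) and PGM2 (YMR105C) rose by 2.22 ± 0.33 and 1.93 ± 0.31 while PGM1 (YKL127W), the minor phosphoglucomutase, changed by -2.31 ± 0.38. Heat-shock chaperones had 9 genes up and 1 down (12 and 1 adjusted over the list alone, median 0.70, adjusted p = 0.0317, and adjusted p = 0.304 with an estimated correlation), and the proteasome 10 of 33 up (14 adjusted over the list alone, median 0.61, adjusted p = 0.0101, and adjusted p = 0.304 with an estimated correlation). Of 5 alpha-specific mating genes, those normally on in cells of the alpha mating type, 3 rose (3 adjusted over the list alone, median 1.63, adjusted p = 0.0135, and adjusted p = 0.125 with an estimated correlation). MF(ALPHA)1 (YPL187W), which encodes the alpha pheromone, rose from 159 ± 26.3 (SD, n = 3) to 1494 ± 727 (SD, n = 2). The a-specific list also lay higher, with AGA2 (YGL032C), MFA2 (YNL145W) and STE2 (YFL026W) past the threshold (5 genes adjusted over the list alone, median 0.76, adjusted p = 0.0127, and adjusted p = 0.189 with an estimated correlation).

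The remaining lists past the day 9 test lay lower. Ribosome biogenesis factors had 3 genes up and 4 down (1 and 1 adjusted over the list alone, median -0.13, adjusted p = 0.000647, and adjusted p = 0.426 with an estimated correlation). Their median was -0.42 on the culture 1 array and 0.15 on the culture 2 array, which had a high ACT1 ratio. RNA polymerase I and III subunits had 1 up and 2 down (1 and 2 adjusted over the list alone, median -0.39, adjusted p = 0.0101, and adjusted p = 0.304 with an estimated correlation). Glycolysis and ethanol fermentation had 1 gene down (1 adjusted over the list alone, median -0.30, adjusted p = 0.00340, and adjusted p = 0.336 with an estimated correlation). Fatty acid beta-oxidation had 3 up and 4 down (5 and 9 adjusted over the list alone, median -0.31, adjusted p = 0.0101, and adjusted p = 0.0854 with an estimated correlation), and G1/S genes 2 up and 3 down (1 and 1 adjusted over the list alone, median -0.16, adjusted p = 0.0160, and adjusted p = 0.419 with an estimated correlation).

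The day 9 array of culture 2 had an ACT1 ratio of 27.0. Without the 3 arrays of high ratio 880 genes passed, 585 higher and 295 lower, of which 531 were among the 842, and the glycogen, chaperone, glycolysis, proteasome and alpha-specific lists lost their calls (adjusted p = 0.0776, 0.246, 0.209, 0.159 and 0.0606). Leaving out chemostat array 1, 2 or 3 gave 387, 469 and 327 genes and leaving out the day 9 array of culture 2 alone gave 491, which also ended the chaperone, glycolysis and proteasome calls (adjusted p = 0.101, 0.229 and 0.0887), as leaving out that of culture 1 ended the ribosome biogenesis, RNA polymerase and G1/S calls (adjusted p = 0.223, 0.183 and 0.159) and leaving out chemostat array 3 the chaperone call (adjusted p = 0.0544). Quantile scaling split the calls into 355 higher and 226 lower, median scaling into 334 and 288, and the glycolysis call ended under quantile scaling. The counts within lists moved as well: under quantile scaling, median scaling and without the 3 arrays, 5, 22 and 21 ribosomal protein genes were lower, 23, 31 and 26 amino acid genes were lower. Higher in the same order were 7, 2 and 6 proteasome genes, 10, 8 and 14 Msn2/4-type stress genes and 6, 5 and 6 chaperones. Under median scaling 7 respiratory chain genes and 2 a-specific genes were higher, and MFA2 lost its call without the 3 arrays (adjusted p = 0.0739). Ribosome biogenesis had 6, 6 and 11 genes lower and 1, 2 and 3 higher, RNA polymerase subunits 4, 4 and 5 lower, and translation factors 2, 2 and 2 lower. Beta-oxidation had 2, 2 and 1 genes higher and 5, 6 and 6 lower, G1/S genes 0, 0 and 2 higher and 2, 4 and 4 lower, and glycolysis 0, 2 and 1 lower.

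On day 16, 1167 genes differed from the chemostat, 926 higher and 241 lower. SNR14 was higher by 4.07 ± 0.34 on the log2 scale, HSP30 by 4.06 ± 0.27 and the tRNA gene SUF1 (YNCO0001C) by 3.76 ± 0.29, the last measured by a probe set shared within its family. FIT2 changed by -4.71 ± 0.32, FIT3 by -4.55 ± 0.88 and FTR1 (YER145C), the high-affinity iron permease, by -3.68 ± 0.39. The core histone list could be measured only through HTB1 (YDR224C) and HTB2 (YBL002W), which encode histone H2B. HTB2 was lower (also adjusted over the list alone), from 1356 ± 165 (SD, n = 3) to 585 ± 139 (SD, n = 2), and the list did not pass (median -0.58, adjusted p = 0.134).

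Amino acid biosynthesis had 26 of 65 genes lower and 2 higher on day 16 (36 and 2 adjusted over the list alone, median -0.95, adjusted p = 2.04e-23). The seripauperin list had 15 of 16 lower (16 adjusted over the list alone, median -1.88, adjusted p = 1.91e-18), ribosomal proteins 13 of 80 lower (10 adjusted over the list alone, median -0.46, adjusted p = 6.23e-15) and ergosterol genes 10 lower and 1 higher (13 and 2 adjusted over the list alone, median -0.88, adjusted p = 5.81e-10). Translation factors had 4 of 32 lower (3 adjusted over the list alone, median -0.34, adjusted p = 1.14e-05). These 5 calls held with an estimated correlation. Glycolysis and ethanol fermentation had 5 of 20 genes lower (7 adjusted over the list alone, median -0.72, adjusted p = 1.93e-06, and adjusted p = 0.264 with an estimated correlation). Its median was -0.21 on the culture 1 array and -1.05 on the culture 2 array, which had the highest ACT1 ratio. Fatty acid beta-oxidation had 5 lower and 3 higher (7 and 3 adjusted over the list alone, median -0.05, adjusted p = 0.0160, and adjusted p = 0.0985 with an estimated correlation). M/G1 and daughter-specific genes had 1 lower (1 adjusted over the list alone, median -0.17, adjusted p = 0.0316, and adjusted p = 0.109 with an estimated correlation). The alpha-specific list had 3 genes higher (3 adjusted over the list alone, median 1.82, adjusted p = 0.0160, and adjusted p = 0.109 with an estimated correlation). The respiratory chain list, with 12 of 34 genes higher, did not pass (median 0.68, adjusted p = 0.0792), and neither did glycogen metabolism (median 0.82, adjusted p = 0.0792).

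The day 16 array of culture 2 had the highest ACT1 ratio, 217. Without the 3 arrays of high ratio 708 genes passed, 514 higher and 194 lower, of which 529 were among the 1167, and the M/G1 list lost its call (adjusted p = 0.205), while 6 more lists passed, among them the respiratory chain list (adjusted p = 0.00452) and the Msn2/4-type stress list (adjusted p = 0.0167). Leaving out 1 day 16 array gave 1757 genes without culture 1 and 406 without culture 2, where the M/G1 call also ended (adjusted p = 0.161), leaving out chemostat array 1, 2 or 3 gave 593, 671 and 537, and quantile and median scaling called 407 and 339 genes higher and 282 and 407 lower. Within lists, quantile scaling, median scaling and the fit without the 3 arrays called 6, 26 and 13 ribosomal protein genes lower, 2, 7 and 0 translation factors lower, 0, 7 and 1 glycolysis genes lower and 11, 0 and 7 respiratory chain genes higher, and HTB2 lost its call without the 3 arrays. Beta-oxidation had 0, 0 and 0 genes higher and 6, 6 and 4 lower, with a median of -0.34 under quantile and -0.42 under median scaling. M/G1 genes had 1, 4 and 3 lower.

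On day 20, the last sampling point, 753 genes differed from the chemostat, 585 higher and 168 lower. The largest fall was in FTR1, from a signal of 1175 ± 65.9 (SD, n = 3) to 74.1 ± 5.87 (SD, n = 2), a log2 difference of -3.99 ± 0.39 (SE, adjusted p = 0.000902). FIT2 changed by -3.88 ± 0.32, FET3 (YMR058W), the iron oxidase that works with FTR1, by -3.05 ± 0.33 and ENB1 (YOL158C), a transporter of the iron carrier enterobactin, by -2.90 ± 0.30. FIT3 changed by -3.14 ± 0.88 (adjusted p = 0.0448), with 894 on the culture 1 array and 317 on the culture 2 array, and lost its call under quantile scaling. Other large falls were in PLB2 (YMR006C, phospholipase B), ALD4 (YOR374W, mitochondrial aldehyde dehydrogenase) and RGI2 (YIL057C, induced in respiratory growth), with -3.66 ± 0.33, -3.26 ± 0.34 and -3.16 ± 0.25.

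With signals under the floor set to it, the largest rise on day 20 was in TKL2 (YBR117C), the minor transketolase, from 12.7 ± 0.693 (SD, n = 3), next to the floor, to 301 and 350 on the day 20 arrays of culture 1 and culture 2, a log2 difference of 4.68 ± 0.43 (SE, adjusted p = 0.000794). HSP30 rose by 3.80 ± 0.27 and the polyamine exporter gene TPO2 (YGR138C) by 3.35 ± 0.23. The mitochondrially encoded genes ATP6 (Q0085) and COX3 (Q0275) were higher by 3.61 ± 0.58 and 3.45 ± 0.62. SNR14 was higher by 3.43 ± 0.34 and the small nucleolar RNA SNR128 (YNCJ0003C) by 3.34 ± 0.31. The tRNA gene YNCM0020W lay under the floor on the 3 chemostat arrays and was at least 10.5-fold higher on day 20 (adjusted p = 0.00140). ATP6 and COX3 lost their calls without the 3 arrays of high ACT1 ratio (adjusted p = 0.0555 and 0.0716).

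**Figure D3:**
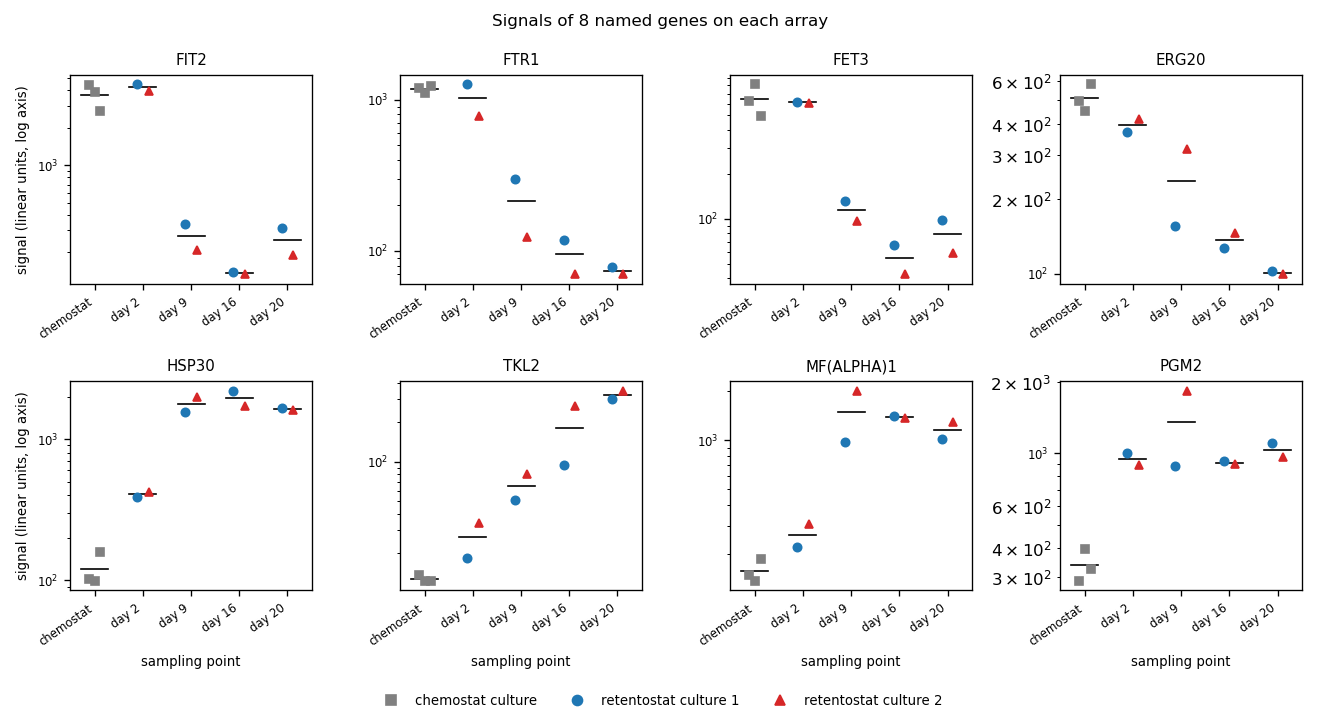
Each panel shows the deposited signal of a named gene on each array, on a log axis, with chemostat cultures as squares, culture 1 as circles and culture 2 as triangles. Bars are the means of the arrays at a sampling point. FIT2, FTR1 and FET3 lay below their chemostat signals on each array of days 9, 16 and 20, while TKL2 ranged from 12.3 to 350.

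Biosynthetic lists were lower on day 20. In amino acid biosynthesis 17 of 65 genes fell and 1 rose (28 and 1 adjusted over the list alone), with a median of -0.65 (adjusted p = 6.10e-24). HIS1 (YER055C), which opens histidine synthesis, HOM3 (YER052C), the aspartate kinase, and ARG1 (YOL058W), of arginine synthesis, changed by -1.86 ± 0.25, -1.56 ± 0.22 and -1.59 ± 0.22. In ergosterol biosynthesis and sterol uptake 9 of 28 genes fell (13 lower and 1 higher adjusted over the list alone), with a median of -0.82 (adjusted p = 1.77e-12). ERG20 (YJL167W), which makes farnesyl diphosphate, changed by -2.32 ± 0.30, ERG28 (YER044C) by -1.56 ± 0.24 and ERG24 (YNL280C) by -1.40 ± 0.22. Of 80 ribosomal protein genes 9 fell (8 adjusted over the list alone), with a median of -0.44 (adjusted p = 2.23e-20), among them RPS22A (YJL190C) with -1.50 ± 0.24, RPL36A (YMR194W) with -1.40 ± 0.26 and RPS1A (YLR441C) with -1.23 ± 0.20. The ribosomal protein median was -0.15 under quantile and -0.87 under median scaling. Translation factors had 1 of 32 lower (1 adjusted over the list alone, median -0.19, adjusted p = 9.83e-05), HYP2 (YEL034W), which encodes eIF5A, with -2.33 ± 0.53. The seripauperin and DAN/TIR list had 10 of 16 lower (12 adjusted over the list alone, median -1.42, adjusted p = 1.32e-18), including PAU13 (YHL046C), PAU15 (YIR041W) and PAU4 (YLR461W) with -2.27 ± 0.27, -1.86 ± 0.25 and -1.69 ± 0.23. The probe sets of these PAU genes are shared within the family, so the signal cannot be assigned to 1 member. These 5 calls held with an estimated correlation.

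Ribosome biogenesis factors had 3 of 107 genes lower and 1 higher on day 20, and none adjusted over the list alone. The lower ones were NOP58 (YOR310C), UTP18 (YJL069C) and HAS1 (YMR290C), with -1.31 ± 0.31, -1.15 ± 0.28 and -1.01 ± 0.29. The list median was 0.08, on the other side of 0 from its test, which placed the list lower than other genes (adjusted p = 0.0191, and adjusted p = 0.657 with an estimated correlation), and the median was -0.32 under quantile and -0.34 under median scaling. The call was lost without chemostat array 3 (adjusted p = 0.0833) or the day 20 array of culture 1 (adjusted p = 0.112). Glycolysis and ethanol fermentation had no gene past the threshold, over all genes or adjusted over the list alone, and a median of -0.33 (adjusted p = 0.000167, and adjusted p = 0.378 with an estimated correlation). Its median was 0.08 under quantile scaling, where the call ended. RNA polymerase I and III subunits did not pass (1 higher and 1 lower, likewise adjusted over the list alone, median -0.16, adjusted p = 0.0621).

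Lists of energy and reserve metabolism lay higher or were mixed. The respiratory chain and ATP synthase list had 4 of 34 genes higher on day 20 (15 adjusted over the list alone, median 0.63, adjusted p = 0.00548, and adjusted p = 0.0845 with an estimated correlation), although the cultures had no oxygen. ATP5 (YDR298C), COX8 (YLR395C) and COX12 (YLR038C) rose by 1.19 ± 0.28, 1.04 ± 0.24 and 0.96 ± 0.22 and lost their calls under median scaling. Glycogen metabolism had 5 of 15 genes higher and 1 lower (8 and 1 adjusted over the list alone, median 0.95, adjusted p = 0.0459, and adjusted p = 0.378 with an estimated correlation). SGA1 (YIL099W), a glucoamylase, PIG2, a likely subunit of the phosphatase that acts on glycogen synthase, and PGM2, the main phosphoglucomutase, rose by 2.14 ± 0.28, 2.12 ± 0.33 and 1.63 ± 0.31, while PGM1 changed by -1.87 ± 0.38. The glycogen call was lost with culture as a random block, without the 3 arrays of high ACT1 ratio (adjusted p = 0.0971), without chemostat array 3 (adjusted p = 0.0796) and without the day 20 array of culture 1 (adjusted p = 0.0571). Fatty acid beta-oxidation and peroxisome genes had 4 lower and 1 higher of 24 (6 and 4 adjusted over the list alone, median -0.16, adjusted p = 0.00260) and kept the call with an estimated correlation. FAA2 (YER015W) and ECI1 (YLR284C), which act on fatty acids, changed by -1.67 ± 0.33 and -1.44 ± 0.25, and PEX7 (YDR142C), an import receptor, by 1.57 ± 0.36, a call that ended under quantile and median scaling.

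Of the cell-cycle and mating lists, those of M/G1 and alpha-specific genes passed. M/G1 and daughter-specific genes had 3 of 23 lower on day 20 (3 adjusted over the list alone, median -0.15, adjusted p = 0.00391), a call that held with an estimated correlation. These were EGT2 (YNL327W), CTS1 (YLR286C) and DSE2 (YHR143W), which act when mother and daughter cells separate, with -1.49 ± 0.21, -1.14 ± 0.29 and -0.96 ± 0.26. CTS1 and DSE2 lost their calls under quantile scaling. The M/G1 median was -0.43 under quantile and -0.58 under median scaling, and -0.01 without the 3 arrays of high ACT1 ratio. The alpha-specific mating list had 3 of 5 genes higher (4 adjusted over the list alone, median 1.63, adjusted p = 0.00631, and adjusted p = 0.0770 with an estimated correlation). MF(ALPHA)1 rose from 159 ± 26.3 (SD, n = 3) to 1152 ± 197 (SD, n = 2), MF(ALPHA)2 (YGL089C) from 10.4 ± 3.59 (SD, n = 3), around the floor, to 40.5 ± 2.97 (SD, n = 2), and STE3 (YKL178C), the receptor for a-factor, by 1.62 ± 0.31 on the log2 scale. The a-specific list had no gene past the threshold and did not pass (none adjusted over the list alone, median 0.35, and -0.07 under median scaling, adjusted p = 0.996). Its member MFA2 gave signals of 5439 and 6662 on the day 20 arrays, above the 1012 and 1291 of MF(ALPHA)1. HTB2 fell by 0.96 on the log2 scale (adjusted p = 0.0485, and also past the threshold adjusted over the list alone), a call that ended under quantile scaling and without the 3 arrays of high ACT1 ratio, and the core histone list did not pass (median -0.52, adjusted p = 0.0942).

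The remaining lists did not pass on day 20, and for oxidative-stress, G1/S, gluconeogenesis, TCA cycle, proteasome, nitrogen, vacuolar and Rim15 signalling genes the sign of the median changed under quantile or median scaling. In these sentences the counts in parentheses are those adjusted over the list alone. Msn2/4-type stress genes had 7 of 39 higher (9 adjusted over the list alone, median 0.46, adjusted p = 0.177), heat-shock chaperones 7 of 24 higher and 1 lower (8 and 1, median 0.60, adjusted p = 0.230), stationary-phase genes 5 of 18 higher and 2 lower (6 and 2, median 0.73, adjusted p = 0.555) and oxidative-stress defence 2 of 28 higher and 4 lower (3 and 4, median 0.26, adjusted p = 0.319). Trehalose metabolism had none (2 higher adjusted over the list alone, median 0.49, adjusted p = 0.432). G1/S genes had 4 of 42 higher (3, median 0.19, adjusted p = 0.555), G2/M genes 4 of 24 higher (5, median 0.45, adjusted p = 0.313) and meiosis and sporulation genes 3 higher and 1 lower (6 and 1, median 0.39, adjusted p = 0.521). Hexose transporters had 1 of 11 higher (1, median 0.44, adjusted p = 0.788), gluconeogenesis and glyoxylate genes 4 higher and 2 lower (4 and 3, median 0.20, adjusted p = 0.230) and the TCA cycle 2 of 15 higher (2, median 0.16, adjusted p = 0.655). Autophagy had 4 of 22 higher (4, median 0.59, adjusted p = 0.294), the proteasome 3 of 33 higher (1, median 0.30, adjusted p = 0.730), nitrogen-catabolite-repressed genes 5 of 27 higher (6, median 0.17, adjusted p = 0.874) and vacuolar hydrolases 1 higher and 1 lower (2 and 1, median 0.04, adjusted p = 0.227). In the Rim15 signalling list none of 22 genes passed, over all genes or adjusted over the list alone (median 0.22, adjusted p = 0.631).

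The day 20 array of culture 2 had an ACT1 ratio of 31.8. Without the 3 arrays of high ratio 301 genes passed, 205 higher and 96 lower, of which 246 were among the 753, and of 47 genes past the threshold that were named for their size or their list's test 15 lost their calls, as did HTB2, which stands outside the 47. The 15 were ATP6, COX3, NOP58, UTP18, HAS1, HYP2, PIG2, CTS1, DSE2, COX8, ATP5, COX12, ECI1, PEX7 and MF(ALPHA)2. The count was 50 without the day 20 array of culture 2, 214 without that of culture 1 and 267, 317 and 288 without chemostat array 1, 2 or 3, and 30 of the 47 lost their calls without some 1 array. Quantile and median scaling called 237 and 191 genes higher and 208 and 319 lower. Under quantile scaling, median scaling and without the 3 arrays, 4, 25 and 7 ribosomal protein genes, 20, 32 and 10 amino acid genes, 8, 14 and 6 ergosterol genes, 2, 5 and 0 translation factors and 1, 5 and 1 M/G1 genes were lower. In the same order 9, 0 and 0 respiratory chain genes, 4, 3 and 2 glycogen genes, 1, 0 and 2 stationary-phase genes, 0, 0 and 1 autophagy genes, 0, 0 and 0 G1/S genes, 6, 3 and 2 chaperones and 6, 3 and 3 Msn2/4-type stress genes were higher. G2/M genes had 1, 1 and 1 higher and meiosis genes 0, 0 and 0. Nitrogen genes had 3, 3 and 2 higher, the proteasome 1, 1 and 2 and the TCA cycle 1, 0 and 0. Ribosome biogenesis had 4, 5 and 0 lower, RNA polymerase subunits 3, 3 and 0, beta-oxidation 5, 5 and 2, gluconeogenesis 5, 5 and 1, oxidative-stress defence 2, 4 and 2 and glycolysis 0, 3 and 1. In the Rim15 signalling list 1 gene was lower under either scaling and 1 higher without the 3 arrays.

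Day 20 was set against day 2 in a fit without a culture term, although both days come from the same retentostat cultures. In it 33 genes differed, 18 higher and 15 lower. FIT2 fell most, from 4214 ± 357 to 251 ± 86.1 (SD, n = 2 each), a log2 difference of -4.11 ± 0.35 (SE, adjusted p = 0.00309), followed by FTR1, FET3 and ENB1 with -3.74 ± 0.43, -3.01 ± 0.36 and -2.51 ± 0.33. PLB2 changed by -2.45 ± 0.36, YMR317W by -2.17 ± 0.36 and INA1 (YLR413W) by -2.07 ± 0.31. SAM4 (YPL273W), a methyltransferase of methionine metabolism, ended under the floor and was at least 4.54-fold lower (adjusted p = 0.00800). TKL2 rose by 3.69 ± 0.47, TPO2 by 2.45 ± 0.25 and MF(ALPHA)1 by 2.13 ± 0.36. The other large rises were in non-coding RNA genes, the small nucleolar RNAs SNR13 (YNCD0030W) and SNR128 with 2.63 ± 0.30 and 2.41 ± 0.34 and the tRNA genes YNCE0008C, SUF6 (YNCN0002C) and SUF1 with 2.66 ± 0.38, 2.46 ± 0.39 and 2.46 ± 0.32. YNCE0008C gave 12.7 and 10.7 on day 2, around the floor, so its rise is a lower bound. YNCM0020W, under the floor on day 2, was at least 10.5-fold higher. A tRNA probe set can be shared within its family, as that of SUF1 is, so such a rise may not belong to 1 gene.

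Ergosterol genes had 1 of 28 past the threshold between day 2 and day 20, ERG20 with -1.97 ± 0.33 (8 lower adjusted over the list alone, median -0.74, adjusted p = 1.97e-15). Amino acid biosynthesis had a median of -0.39 with none past (none adjusted over the list alone, adjusted p = 7.96e-15), the seripauperin list -0.72 (3 lower adjusted over the list alone, adjusted p = 7.44e-12) and M/G1 genes -0.28 (2 lower adjusted over the list alone, adjusted p = 7.37e-05). These 4 calls held with an estimated correlation. Ribosomal proteins had -0.16 (adjusted p = 6.40e-06, and adjusted p = 0.0563 with an estimated correlation), and their median was 0.04 under quantile scaling. Glycolysis had -0.26 (adjusted p = 0.000250, and adjusted p = 0.276 with an estimated correlation) and beta-oxidation genes -0.09 (adjusted p = 0.00205, and adjusted p = 0.0505 with an estimated correlation). Translation factors had -0.11 (adjusted p = 0.00579, and adjusted p = 0.0642 with an estimated correlation) and Msn2/4-type stress genes -0.05 (adjusted p = 0.0142, and adjusted p = 0.276 with an estimated correlation). The alpha-specific list was higher with a median of 1.15 and MF(ALPHA)1 past the threshold (4 genes adjusted over the list alone, adjusted p = 0.00227, and adjusted p = 0.0563 with an estimated correlation). None of the last 5 lower lists had a gene past the threshold, over all genes or adjusted over the list alone. The ribosomal protein, translation, stress and glycolysis lists lost their calls under quantile scaling, the stress list also without the day 2 array of culture 1 (adjusted p = 0.312) or the day 20 array of culture 2 (adjusted p = 0.0890) or without the 3 arrays of high ACT1 ratio (adjusted p = 0.0595), and the translation list without the day 2 array of culture 2 (adjusted p = 0.0689).

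The retentostat days share their cultures, and with culture as a random block the day 20 against day 2 count was 149, 104 higher and 45 lower. It was 40 with culture as a fixed term within the retentostat arrays and 52 with the replicate number as a fixed term. It was 4 without the 3 arrays of high ACT1 ratio, and of the 18 named genes YNCM0020W, SUF1 and PLB2 remained past the threshold. With all arrays 758 genes had an unadjusted p under 0.05. The count of calls was 0 without the day 2 array of culture 1 or the day 20 array of culture 2, 5 and 4 without the day 2 array of culture 2 or the day 20 array of culture 1, 65 without either day 16 array and 19, 21 and 15 without chemostat array 1, 2 or 3. Quantile and median scaling called 13 and 14 genes higher and 16 and 33 lower.

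Between day 2 and day 9, 9 genes differed, 4 higher and 5 lower. MF(ALPHA)1 rose by 2.43 ± 0.36, HSP30 by 2.12 ± 0.30 and ATG45 (YIL024C) by 1.87 ± 0.25 on the log2 scale, each with an adjusted p of 0.0413. FIT2, FET3 and ENB1 changed by -3.98 ± 0.35, -2.43 ± 0.36 and -2.24 ± 0.33. With culture as a random block 65 genes passed, 28 higher and 37 lower, and with culture or the replicate number as a fixed term 1 and 5 passed. Without the 3 arrays of high ACT1 ratio the count was 0 by limma, with each of these 6 calls lost and 812 genes at an unadjusted p under 0.05 with all arrays. It was 2 under quantile scaling, both lower, with FIT2 the only named gene among them, 13 under median scaling, 3 higher and 10 lower, and 0 or 4 without the day 2 array of culture 1 or 2, 2 without either day 9 array, 1 without either day 20 array and 1, 4 and 1 without chemostat array 1, 2 or 3.

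Between day 9 and day 20 no gene passed in limma's test, and 419 genes had an unadjusted p under 0.05. The smallest p-values belonged to SVS1 (YPL163C) and CIS3 (YJL158C), which encode cell-wall proteins, to the tRNA genes SUP51 (YNCJ0021C) and YNCE0008C and to CYC7. Their log2 differences were 2.25 ± 0.34, 1.53 ± 0.27, 2.11 ± 0.32, 2.35 ± 0.38 and -1.53 ± 0.27, with adjusted p-values from 0.221 to 0.239. With culture as a random block 3 genes passed, all higher, and these were SVS1, SUP51 and YNCE0008C, while 0 passed with culture or the replicate number as a fixed term. The count was also 0 without the 3 arrays of high ACT1 ratio.

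FMP16 was higher than in the chemostat on each of the 4 retentostat days, and no gene was lower on all 4. Because day 2 had 1 call, the overlap was also counted for days 9, 16 and 20, a choice made after the data were seen. On these 3 days 352 genes were higher and 118 lower throughout. The comparisons share the 3 chemostat arrays. Days 9, 16 and 20 also share their 2 retentostat cultures. In 50 simulations of unchanged groups, which hold no effect and no shared retentostat culture, the mean overlap was 0 in both directions. Without an effect few calls are made after adjustment, so this 0 gives no baseline for lists of the observed sizes. Independent lists of the observed sizes would share 11.1 higher and 0.267 lower genes. Part of the excess over independent lists may come from the shared chemostat arrays, which were too few to split, or from the shared cultures. The overlap was 137 higher and 81 lower genes without the 3 arrays of high ACT1 ratio. Of the 470 genes in both directions, the count was 189, 231 and 180 without chemostat array 1, 2 or 3 and 179 and 47 without the day 20 array of culture 1 or 2, and the FMP16 overlap ended without any 1 array.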

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

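The tests of the pattern in culture 2 were chosen after the ACT1 ratios were seen, and their outcomes were not known then; the fits without the 3 arrays were added after the data were seen. The signal ratio between the 3' and the 5' end of ACT1, read from control probe sets that the gene tests do not use, was 27.0 on the day 9 array of culture 2, 217 on its day 16 array and 31.8 on its day 20 array, above the highest chemostat value of 1.31. The ratio for MED17 was 17.6, 17.7 and 17.3 on the same arrays and 2.49 to 6.40 on the others, and that for SPT15 was 24.7 on the day 16 array of culture 2 and 0.909 to 4.90 on the others.

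Replicate arrays correlated at 0.886 on day 9 and 0.853 on day 16, below the 0.959 of day 2, while day 20, whose culture 2 array also had a high ratio, gave 0.965, so a high ratio did not always go with a low correlation. A swap of labels with the chemostat or day 2 was tested by the best match of each of the 3 arrays. Each matched an array of day 9, 16 or 20 best. For the day 9 and day 16 arrays this was another of the 3, which a shared high ratio or culture could produce. Against arrays without a high ratio, the day 9 array gave 0.9269 (culture 1, day 20) and 0.9261 (culture 2, day 2). The day 16 array gave 0.8798 and 0.8648 with the same arrays. The match therefore cannot decide on a swap for the day 9 and day 16 arrays. The day 20 array matched the culture 1 array of day 20 best (0.9646), which argues against a swap for it. Loss of 5' signal could lower long transcripts more than short ones, and the correlation across genes between coding length and the difference of culture 2 from culture 1 was 0.0149 on day 9, -0.02 on day 16 and -0.08 on day 20, against 0.00942 on day 2. The last lay between the bounds set for and against this explanation, so loss of 5' signal and a difference between the cultures cannot be told apart, and no biological explanation was tested.

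The change from the chemostat differed between day 2 and day 20 for 33 genes, by the test of day 20 against day 2. Among probe sets annotated to several genes, which the gene test left out, 56 of 317 differed from the chemostat on day 20, 17 higher and 39 lower. Among probe sets without a gene name, 235 of 1869 did, 184 higher and 51 lower.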

How the results depend on the processing

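The fits without the 3 arrays of high ACT1 ratio, the ratio as a covariate and the overlap of days 9, 16 and 20 were chosen after the result was seen; the other alternatives were not. No list past its camera test, and no called gene named for its size or its list's test, passed in the opposite direction under the settings it was run with. Single genes and lists were not rerun with log2(signal + 32), all probe sets, the intensity trend, the fixed terms, a culture left out or only the groups compared, nor single genes with the ratio as a covariate. Fry called oxidative-stress and Rim15 signalling genes (days 9, 16 and 20), nitrogen genes (days 16 and 20) and G2/M genes (day 16) higher where camera placed them lower without a call. The balance of calls did turn: median scaling gave 339 higher and 407 lower genes on day 16 and 191 higher and 319 lower on day 20. List medians changed sign for ribosome biogenesis on day 20 (-0.32 under quantile scaling), glycolysis on day 20 (0.08) and ribosomal proteins from day 2 to day 20 (0.04). For the counts listed here the cause was not tested, except that leaving out arrays or genes changes how much is tested. Of the calls of genes named for their size or their list's test, 14 were lost under quantile scaling, 6 under median scaling, 2 with log2(signal + 1) and 37 without the 3 arrays of high ratio, and 3 were gained with the culture block. Genes that could be named in any case, such as SCH9 and HTB2, are not in these counts, and the losses among them given in the report come on top. Of the list results, 38 were lost with an estimated correlation, and fry lost 15 and gained 39. With all arrays, limma gave an unadjusted p under 0.05 for 478 genes on day 2, 758 for day 20 against day 2, 812 for day 9 against day 2 and 419 for day 20 against day 9. The share of probe sets at or under the floor, 15.8% to 22.9% per array, limits what can be seen of weak transcripts.

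Quantile scaling gave 377 genes over the 5 sampling points, 0 on day 2, 689 on day 16, 445 on day 20, 2 for day 9 against day 2, 0 shared by all 4 days and 291 shared by days 9, 16 and 20, and 16 lists on day 16. Median scaling gave 422 genes over the sampling points, 0 on day 2, 746 on day 16 and 0 shared by all 4 days. On day 2 and for all 4 days, log2(signal + 1) gave 0 and 0, log2(signal + 32) 3 and 3, all probe sets 6 and 6, and the intensity trend with robust estimation 0 and 0. For day 9 against day 2, log2(signal + 32) gave 17, and for day 20 against day 2 all probe sets gave 53.

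The replicate block, with culture as a random effect, gave 149 genes for day 20 against day 2, 65 for day 9 against day 2 and 3 for day 20 against day 9. With the replicate number as a fixed term the counts were 399 over the sampling points, 0 on day 2, 52 for day 20 against day 2, 5 for day 9 against day 2 and 0 shared by all 4 days. Culture as a fixed term within the retentostat arrays gave 40 for day 20 against day 2 and 1 for day 9 against day 2, and neither fixed term called a gene for day 20 against day 9. Only the arrays of the groups compared gave 0 on day 2, 758 on day 16, 1942 on day 20, 0 for day 20 against day 2 and 0 for day 9 against day 2.

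With culture 1 left out, 1079 genes changed over the sampling points, 0 on day 2, 1461 on day 9, 2349 on day 16, 0 for day 20 against day 2 and 0 for day 9 against day 2, with 0 shared by all 4 days and 747 by days 9, 16 and 20. With culture 2 left out, the counts were 0 over the sampling points, 0 on day 2, 655 on day 16, 241 on day 20, 0 for day 20 against day 2 and 0 for day 9 against day 2, with 0 and 173 shared. Each day then had 1 array, assumed to vary like the chemostat.

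Without the 3 arrays of high ratio, limma gave 175 over the sampling points, 0 on day 2, 708 on day 16, 301 on day 20, 4 for day 20 against day 2 and 0 for day 9 against day 2, with 0 and 218 shared and 14 lists on day 16. The log2 ratio as a covariate gave 30 on day 2, 1365 on day 9, 1254 on day 20, 149 for day 20 against day 2, 94 for day 9 against day 2 and 7 for day 20 against day 9, with 28 and 717 shared.

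Leaving out each array in turn gave 156 to 1060 genes over the sampling points, 0 to 0 on day 2, 327 to 1089 on day 9, 406 to 1757 on day 16 and 50 to 1069 on day 20. It gave 0 to 65 for day 20 against day 2, 0 to 7 for day 9 against day 2, 0 to 0 for day 20 against day 9, 0 to 0 shared by all 4 days and 47 to 559 shared by days 9, 16 and 20. A day left with 1 array is assumed to vary like the other groups. List counts ran from 9 to 16 on day 2, 14 to 17 on day 9, 9 to 15 on day 16, 10 to 13 on day 20 and 9 to 11 for day 20 against day 2. Without dim genes 9 lists passed on day 2, the estimated correlation left 4 on day 2, 5 on day 9, 5 on day 16, 7 on day 20 and 4 for day 20 against day 2, and fry gave 23 on day 16 and 21 on day 20.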

Other observations

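The gene groups in this part were chosen after the results of single genes were seen, so their tests were chosen after that too. Small non-coding RNA genes, 143 in all, of which 55 encode small nuclear or nucleolar RNAs and 88 tRNAs, lay higher on days 9, 16 and 20 than in the chemostat. Their median log2 difference from the chemostat was 0.18 on day 2, 0.69 on day 9, 1.45 on day 16 and 1.14 on day 20, with 40, 91 and 65 genes higher past the threshold on days 9, 16 and 20. Without the 3 arrays of high ACT1 ratio these counts were 38, 60 and 31, and under quantile scaling 35, 64 and 41. On day 20 camera gave an adjusted p of 4.23e-14, but with an estimated correlation the adjusted p was 0.292, 0.0726 and 0.105 on days 9, 16 and 20, so the calls of the class were lost. Probe sets of tRNA genes can be shared within a family, so the 88 tRNA genes need not be separate measurements. The labels describe an mRNA isolation, and how the small non-coding RNAs passed it was not tested.

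A pair of technical accounts of this rise was set against the data. Loss of 5' signal on the arrays of culture 2 would leave culture 1 unchanged, but the median on the culture 1 array of day 20 was 0.97, against 1.45 on that of culture 2 and at most 0.05 on a chemostat array. A rise made wholly by the scaling would be lost under other scalings. The lowest median under quantile and median scaling was 0.88, below the 1.14 as deposited but not lost. These values argue against either account as the explanation of the whole rise. A part of the rise may still come from either. Members named above were weak in the chemostat, with signals of 18 to 38.6 for SNR14 and 1.4 to 1.9, under the floor, for YNCM0020W. The rise was not compared with that of equally weak coding genes, so a general lift of weak signals stays open. A higher share of small non-coding RNA in the RNA of slowly dividing cells may be a candidate explanation, and unequal mRNA isolation between samples stays open, untested.

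A list of 20 iron uptake genes was written after FIT2, FIT3, FTR1, FET3 and ENB1 were seen among the falls, so a test of the whole list restates what was seen. The other 15 members had a median log2 difference from the chemostat of -0.01 on day 20, with 6 of them above 0, and of -0.42 under quantile and -0.43 under median scaling. Their median was 0.44 on day 2, -0.20 on day 9 and -0.47 on day 16, when 2 were lower and 1 higher past the threshold. It was -0.42 on day 9 under either scaling and, on day 16, -0.76 under quantile and -0.84 under median scaling. Of the 15, FRE5, a reductase, passed on day 20 with -2.05 (adjusted p = 0.00425). SIT1, TIS11 and ARN1 gave -1.81, -1.09 and -0.95 and FRE3, FIT1 and FTH1 gave 1.06, 0.85 and 0.73, none of them past the threshold. From day 2 to day 20 the 15 had a median of -0.23, and of -0.51 under quantile and -0.53 under median scaling. Of the whole list 4 genes were then lower, and these calls ended without the 3 arrays of high ACT1 ratio, where fewer arrays were left, although the list median was -1.06 with all arrays and -1.08 without the 3.

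For the whole iron list on day 20, the weakest median under quantile and median scaling was -0.81, against -0.46 as deposited. The day 20 median of all genes was 0.36 as deposited, 0.07 under quantile and -0.04 under median scaling. Rescaling therefore lowered medians in general, and no conclusion on the deposited scaling is drawn from this test. Against loss of 5' signal, the bound was set on the list's median on the culture 1 array of day 20, -0.61. That bound was ill chosen, since the genes seen beforehand carry this median and the other 15 gave 0.01 on the same array. On it the 5 genes seen beforehand changed by -2.39 to -3.91. Genes named for day 20 had to show no overlap between the arrays of the groups. A fall on this array, though not its size, was thus fixed beforehand, and it is no independent test of this explanation. For the list as a group, loss of 5' signal and a fall in the cells cannot be told apart by a median that these 5 carry, and no biological explanation was tested.

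Mitochondrially encoded genes, 16 measured, had a median of 0.24 on day 20 with 7 higher (camera adjusted p = 0.237), and 1 was higher without the 3 arrays of high ACT1 ratio. From day 2 to day 20 they lay higher, with no gene past the threshold in limma (camera adjusted p = 6.03e-05, and adjusted p = 0.0938 with an estimated correlation). The median of that difference was 1.18 without the 3 arrays (camera adjusted p = 0.00224) and close to it with all arrays. On day 2 the median against the chemostat was -0.07 (camera adjusted p = 0.0177, and adjusted p = 0.677 with an estimated correlation).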
